A study of Mus musculus with 6 samples.

How the data were processed

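Gene expression was measured by RNA sequencing in 6 libraries of intestinal epithelium, each from a different mouse, 3 control and 3 knockout. The sample titles name jejunum, while the series text describes segments 10 cm long of jejunum and ileum, from animals that were co-housed and, per the labels, aged 3 to 4 months. The wash held 0 mM glucose per the labels and 10 mM per the series text. In it, epithelial cells were released with EDTA and dithiothreitol, collected and lysed in TRIzol. The labels name poly-A selection and also a kit that removes ribosomal RNA, so which step set the RNA composition is not settled by them. Per the submitters' processing notes, bcl2fastq 2.17, FastQC, Trim Galore and STAR 2.5.0a were used with the mouse build mm10. The read counter, its strand setting and the annotation release are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart.

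The authors deposited whole-number read counts per gene and library, with no normalization, for 54446 genes, each with an Ensembl identifier, a biotype, a symbol and a location. Of these identifiers, 53229 (97.8%) matched GENCODE mouse release 21 with their version, and all 53229 had the coordinates of that release. Coordinates are given on mm10, counted from 1, and span whole genes, because the counts carry no exon or transcript. Groups and replicate numbers came from the sample titles, and sexes from the series text.

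From the deposited counts, genes were tested with edgeR 4.0.16 in R 4.3.3, using trimmed-mean scaling, the tool's default expression filter (minimum count 10), and the two-sided quasi-likelihood F test with genotype as the sole term. This left 15068 genes. P-values were adjusted by the Benjamini-Hochberg method, and 0.05 was the threshold. CPM is the scaled count divided by the scaled library total, times 1e6, and a standard error is the log2 fold change divided by the square root of F. Counting intervals are exact and cover 95% of counting error alone, since reads without molecular identifiers are not independent molecules. Per-library values were compared with an exact two-sided permutation test, for which 3 against 3 libraries cannot give a p below 0.1.

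The 54 gene lists, with 1402 entries, covered pathways, epithelial lineages, intestinal regions, other cell types and RNA quality, and were fixed before the data were examined, as were the main test and the first set of alternatives named below. Lists were tested with camera (limma 3.58.1) at its preset inter-gene correlation of 0.01, adjusted over the 54 lists. Camera with an estimated correlation and fry were the alternatives. Members were counted both over all genes and adjusted over the list alone. A list level is the mean log2 CPM of its members (prior count 2) minus the mean of the controls.

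Genes were named by a rule fixed in advance, namely Prkci, up to 10 called genes in each direction with a mean of at least 2 CPM and no overlap between genotypes, up to 3 called members of each list, the most abundant member of a list without a call, and Xist with Ddx3y. Not every gene that this rule chose is reported here. Because few members were called over all genes, up to 3 members past the threshold within their list were added after their values were seen, as were the genes of the closing section that lie outside those lists.

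The replicate numbers shared by the genotypes were checked as a possible pairing. Deviations from the group means correlated at 0.117, 0.119 and 0.149 across genes for libraries of the same number, against −0.143 to 0.00929 for the other pairs. All 3 exceeded 0.1, so by this rule the value with the replicate block is given where it ended a call or moved a count by more than 1.5 times. The main tests kept genotype as the sole term. No label says what a number marks. Deviations within a group sum to 0, so positive values for the same number lower those of the other pairs. These correlations therefore do not establish a pairing. No 2 libraries of a group agreed within sampling noise, the lowest chi-square per gene being 23.8.

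Alternatives were DESeq2 size factors, library totals, no filter, a filter of 1 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the replicate block, sex from the series text as a covariate, the males of the series text alone, a test against a fold of 1.5, and leaving out each library. Sex by Xist and Ddx3y, protein-coding genes alone, leaving out the 3 libraries whose Xist went against the series text, and the newer edgeR dispersion estimation were added after seeing the data. The gene tests were tested on simulated data for the knockout against control comparison, with counts drawn for 15068 genes in 5 sets and the changed genes split between folds of 2 and 4. Of the genes changed by a fold of 2, edgeR recovered 28% and DESeq2 53.8%, and of those changed by a fold of 4, 80% and 86%. False calls made up 5.26% of edgeR calls and 22.0% of DESeq2 calls. Camera recovered 50 of 50 lists shifted by a fold of 1.5 and called 6 of 158 that were not shifted. Each gene was drawn independently, so the simulated lists held no correlation between genes. In the real libraries the estimated correlation was 0.502 for the interferon-gamma list and 0.902 for the tuft list. The simulation therefore does not give the rate of false camera calls in these data.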

Results

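Prkci encodes atypical protein kinase C iota/lambda, a kinase of the apical polarity complex. The series compared transcripts of intestinal epithelium from mice with floxed Prkci alleles (control, n = 3) and from mice that also carried Villin-Cre, a recombinase expressed in intestinal epithelium (knockout, n = 3). The question was how loss of the kinase alters transcripts of enterocytes. Total counts were 22453798, 22511957 and 23008047 in control replicates 1 to 3, and 18972906, 25258885 and 26687856 in knockout replicates 1 to 3.

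Prkci (ENSMUSG00000037643.14, chromosome 3, 30995747 to 31052959) was lower in each knockout library than in any control. It stood at 44.6, 46.9 and 44.0 CPM in the controls (mean 45.2 ± 1.53, SD, n = 3) and at 21.5, 14.6 and 21.4 CPM in the knockouts (19.2 ± 3.97, SD, n = 3). The knockout to control ratio was 0.423, with a counting interval of 0.396 to 0.452. The log2 fold change was −1.24 (SE 0.17), with an edgeR adjusted p of 0.0719, which did not pass the threshold. Over the alternatives with more than 1 control, the adjusted p ran from 9.91e-08 with DESeq2 to 0.486 with the males of the series text. It was 0.00345 without knockout replicate 1. Counts over the whole gene include exons outside the deleted part and cells without Cre.

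The 3 control libraries lay close together on the first principal component (54.7% of the variance), at −33.3, −33.3 and −30.4, and knockout replicates 2 and 3 lay at 68.0 and 50.9. Knockout replicate 1 lay at −21.9, nearer to the controls, and stood apart on the second component (20.2%) at −52.6. Xist, the transcript of the inactive X chromosome, had 9, 12 and 31810 counts in control replicates 1 to 3 and 10, 23534 and 33757 in knockout replicates 1 to 3. Ddx3y, a gene of the Y chromosome, had 1246, 1068 and 1 counts and 1019, 0 and 0 counts in the same order. These counts went against the sex given in the series text for control replicates 2 and 3 and knockout replicate 3. By these transcripts, 1 control and 2 knockout libraries came from females. Without knockout replicate 1, the knockouts left were both female by Xist, against 1 of the 3 controls. Results of that set therefore do not part genotype from sex. Gm26917 and Gm42418, loci that overlap ribosomal RNA repeats, took 2.55% ± 0.376 of counts in controls and 5.41% ± 0.511 in knockouts (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). Vim, a mesenchymal and leukocyte filament gene, had 2.66 ± 0.151 counts per 1000 counts of the epithelial keratin Krt8 in controls and 4.74 ± 0.848 in knockouts (SD, n = 3 each, exact permutation p = 0.1, the smallest possible).

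**Figure D1:**
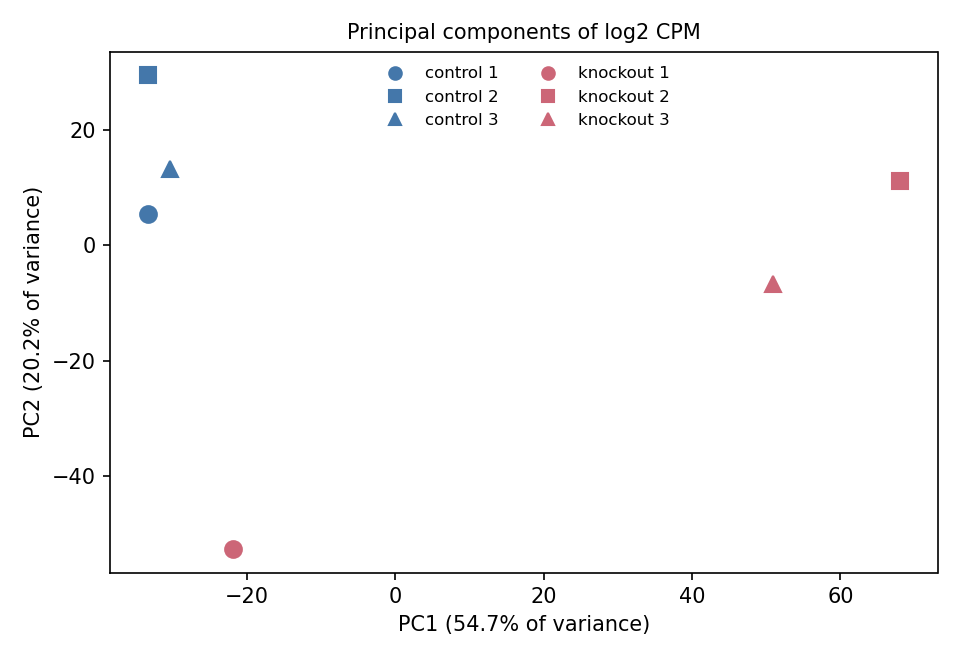
Position of each library on the first and second principal components of log2 CPM. The controls lie between −33.3 and −30.4 on the first component, knockout replicates 2 and 3 at 68.0 and 50.9, and knockout replicate 1 at −21.9.

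Between the genotypes, 8 genes rose and 1 fell among the 15068 tested. Tlr4, the receptor for bacterial lipopolysaccharide, rose from 0.706 ± 0.0784 to 8.95 ± 2.36 CPM (SD, n = 3 each), and Aim2, a cytosolic sensor of double-stranded DNA, rose from 2.95 ± 0.464 to 16.5 ± 0.219 CPM. Anxa10, an annexin expressed in gastric epithelium, had 3 counts in all controls and 347 in all knockouts, a ratio of 121 with a counting interval of 40.9 to 588. The homeobox gene Msx1 rose 30.5-fold from 0.171 CPM, and the surface antigen gene Ly6d rose 9.24-fold from 0.580 CPM. Pipox, a peroxisomal oxidase of sarcosine and pipecolic acid, fell from 27.1 ± 2.51 to 5.90 ± 1.33 CPM.

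By edgeR, log2 fold changes were 3.65 for Tlr4 (SE 0.28, adjusted p = 0.0142), 2.49 for Aim2 (SE 0.17, adjusted p = 0.0142), 4.93 for Msx1 (SE 0.38, adjusted p = 0.0142), 3.21 for Ly6d (SE 0.29, adjusted p = 0.0232) and −2.20 for Pipox (SE 0.20, adjusted p = 0.0232). Capn2, a calpain protease, rose by 2.18 (SE 0.23, adjusted p = 0.0460), the actin crosslinker gene Flna by 1.77 (SE 0.18, adjusted p = 0.0381), and Prdm1, which encodes the repressor Blimp-1, by 1.17 (SE 0.12, adjusted p = 0.0460). Each of the 9 genes was separated between the genotypes in all 6 libraries. Tlr4 lies on chromosome 4 (66827584 to 66930284), Aim2 on chromosome 1 (173350879 to 173466040), Msx1 on chromosome 5 (37820485 to 37824583), Anxa10 on chromosome 8 (62057042 to 62123150), and Pipox on chromosome 11 (77880615 to 77894096). At an unadjusted p below the threshold there were 2473 genes, 1405 higher and 1068 lower, where 753 were expected by chance. Other splits of the same 6 libraries into 3 and 3 gave from 98 to 2277 such genes. The highest of these put control replicates 1 and 3 together with knockout replicate 1. An excess over 753 is therefore not particular to the split by genotype. The groups did not overlap for 21.8% of genes, against 10% by chance. The count depended on the libraries and the tool. It was 0 with the replicate block, 839 with DESeq2 (544 higher, 295 lower), 0 without control replicate 1, 2 or 3 or knockout replicate 3, and 2700 (1549 higher, 1151 lower) without knockout replicate 1, and library totals without scaling gave 11 higher and 5 lower.

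**Figure D2:**
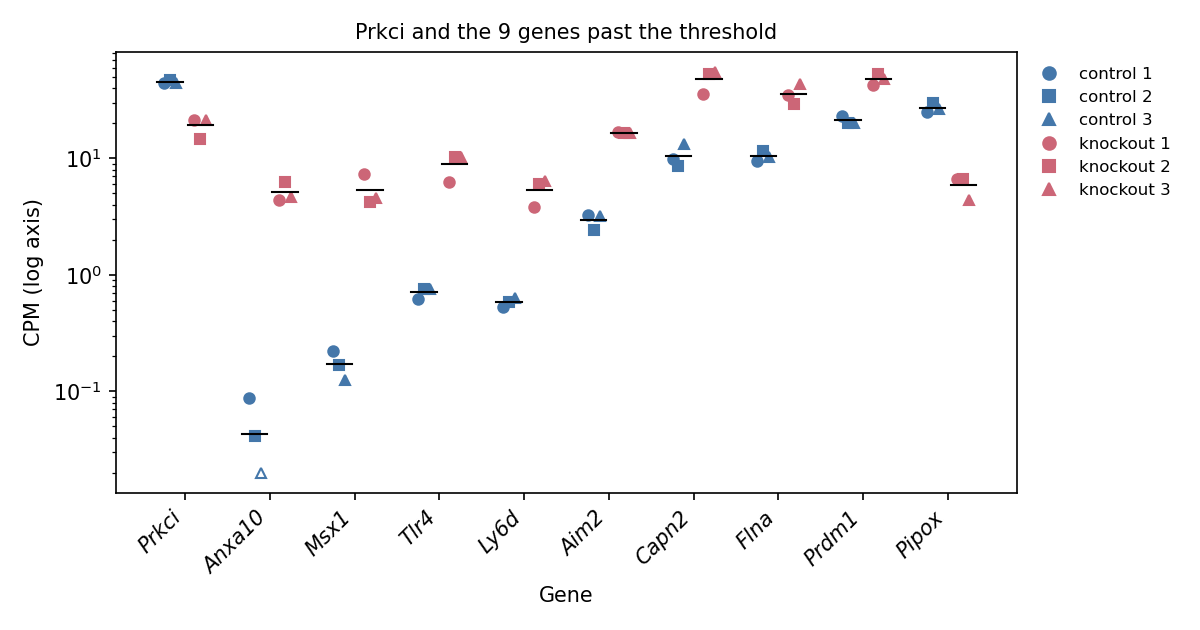
CPM on a log axis of Prkci and the 9 genes past the threshold in each library, with a line at each group mean. An open symbol drawn at the foot of the axis marks a count of 0. For each of these genes the 3 knockout libraries lie on one side of the 3 controls.

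Genes of the interferon-gamma response were higher in the knockouts. Of 23 measured members of the list of interferon-gamma GTPases and related genes, 0 passed the edgeR threshold over all genes tested, against 18 by DESeq2, and 20 by edgeR without knockout replicate 1. Adjusted over the list alone, 20 rose by edgeR (20 at an unadjusted p), with a median log2 fold change of 1.67 over the list. Gbp2, a guanylate-binding GTPase of cell-autonomous defence, rose within the list by a log2 fold change of 3.92 (SE 0.63) from 1.98 ± 0.702 CPM (SD, n = 3), to 8.70, 45.4 and 35.9 CPM in knockout replicates 1 to 3. Gbp9 rose from 2.28 to 6.26 CPM and the T cell chemokine gene Cxcl9 from 0.538 to 5.39 CPM within the list. Nos2, the most abundant member, overlapped between genotypes. It stood at 38.1, 818 and 487 CPM in knockout replicates 1 to 3, against 44.3, 15.8 and 15.1 CPM in the controls. The list level was 0.89 in knockout replicate 1, 2.33 in replicate 2 and 2.00 in replicate 3. Camera placed the list higher (adjusted p = 1.17e-23), and adjusted p = 0.396 with an estimated correlation. Leaving out any 1 library left between 19 and 22 members past the threshold, and the replicate block left 19.

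Interferon-stimulated genes and genes of MHC class I presentation were also higher, by smaller amounts. Over the list alone, 16 of 45 interferon-stimulated genes rose, among them Zbp1, a sensor of Z-form nucleic acid (24.1 ± 3.37 to 92.2 ± 47.9 CPM, SD, n = 3 each), and Ifit2 (2.13 to 7.79 CPM). Of 26 MHC class I genes, 11 rose, among them Nlrc5, the transactivator of MHC class I (9.36 ± 2.27 to 51.1 ± 17.6 CPM), and H2-Q7 (5.31 to 25.6 CPM), whose reads are hard to part from those of its close copies such as H2-Q6. Ciita, the transactivator of MHC class II, rose from 51.3 to 82.8 CPM and was the 1 of 10 MHC class II genes past the threshold. The most abundant interferon-stimulated member, Ifi27l2b, was 1 of 3 with a negative fold (469 and 446 CPM), against 42 with a positive one. B2m, the most abundant MHC class I member, overlapped between genotypes (1226 ± 133 and 1827 ± 507 CPM). Cd74, that of MHC class II, was 1.41-fold higher without overlap. By edgeR none of the members of these 3 lists passed over all genes tested (28, 16 and 6 at an unadjusted p), while by DESeq2 15, 11 and 1 did. Camera gave adjusted p = 9.34e-14, 2.97e-13 and 0.000349 for the 3 lists, and adjusted p = 0.436 for each with an estimated correlation. The replicate block left 3 interferon-stimulated and 7 MHC class I genes. Without control replicate 1, control replicate 2, knockout replicate 2 or knockout replicate 3, the interferon-stimulated count was 0, 0, 1 and 0, and without control replicate 2, control replicate 3, knockout replicate 2 or knockout replicate 3 the MHC class I count was 5, 4, 6 and 4; without knockout replicate 1 the counts were 30 and 22. The MHC class II count was 0 without control replicate 2, control replicate 3 or knockout replicate 3, and 8 without knockout replicate 1.

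Genes of innate sensing rose in part. Of 25 pattern recognition genes, 8 rose over the list alone, among them Tlr4, which also passed over all genes, Tlr1 (2.52 ± 0.127 to 9.62 ± 3.76 CPM, SD, n = 3 each) and Tmem173, which encodes STING (1.63 to 6.10 CPM). Of 33 NF-kB targets and cytokines, 6 rose, among them the adhesion gene Icam1 (0.953 to 3.40 CPM) and the chemokine gene Cxcl16 (28.6 to 54.8 CPM). In the list of inflammasome and necroptosis genes, Aim2, Ripk3, Mlkl and 1 more member rose and Naip2 fell, of 21 measured. Ripk3, a kinase of necroptosis, rose by a log2 fold change of 1.19 (SE 0.20) to 50.1 ± 13.3 CPM (SD, n = 3), and Naip2, a sensor of bacterial proteins, fell from 126 to 95.9 CPM. Camera gave adjusted p = 3.13e-06 for pattern recognition, 2.73e-05 for NF-kB targets and 0.0704 for the inflammasome list (0.0433 without control replicate 3), and adjusted p = 0.373, 0.436 and 0.436 with an estimated correlation. With the replicate block, 4 pattern recognition genes and 2 inflammasome genes were left. The pattern recognition count was 5, 3 and 3 without control replicate 1, 2 and 3, and 4 and 3 without knockout replicate 2 and 3. For NF-kB targets it was 0 without control replicate 3. In the inflammasome list 2 rose and 0 fell without control replicate 1, 2 or 3 or knockout replicate 2, and 4 rose and 0 fell without knockout replicate 3. Without knockout replicate 1, 12 rose and 1 fell, 11 rose and 2 fell, and 7 rose and 4 fell in the 3 lists.

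**Figure D3:**
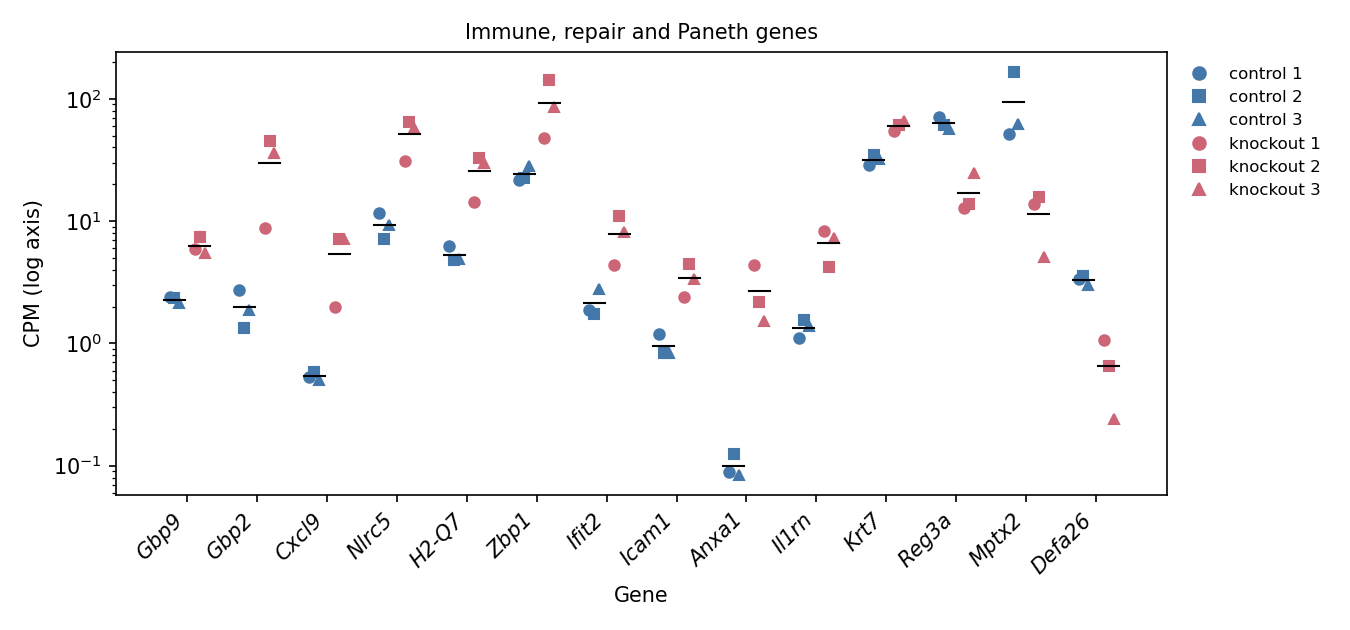
CPM on a log axis of named immune, repair and Paneth genes in each library, with a line at each group mean. Knockout libraries lie above the controls for Gbp9 to Krt7 and below them for Reg3a, Mptx2 and Defa26.

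Genes linked to fetal-like epithelium and repair were higher in part, with a list mean of similar size in the 3 knockouts. Of 20 measured members, Anxa10 passed over all genes and 11 rose over the list alone. Anxa1, an annexin of epithelial repair, went from 0.0989 ± 0.0227 to 2.68 ± 1.48 CPM (SD, n = 3 each), the interleukin-1 receptor antagonist gene Il1rn from 1.34 to 6.57 CPM, and Krt7, a simple-epithelium keratin, from 31.7 to 60.4 CPM. The list level was 1.04, 1.17 and 1.20 in knockout replicates 1 to 3. Camera gave adjusted p = 1.17e-13, and adjusted p = 0.0575 with an estimated correlation, while fry gave 0.0115. With any 1 library left out, between 9 and 13 members rose, and 2 fell without knockout replicate 1 (0 in the full set).

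Paneth cell genes were lower in the knockouts. Of 20 measured members, 6 fell by edgeR over the list alone and 0 over all genes (10 at an unadjusted p, and 5 over all genes by DESeq2), with a median log2 fold change of −1.53. Mptx2, a mucosal pentraxin, went from 93.5 ± 63.5 to 11.5 ± 5.62 CPM (SD, n = 3 each), and the alpha-defensin genes Defa26 and Defa30 from 3.31 to 0.652 and from 275 to 41.4 CPM. Alpha-defensins are near-identical copies, so the split of reads among them is uncertain. Camera gave adjusted p = 3.47e-09 for Paneth genes, and adjusted p = 0.404 with an estimated correlation. Without control replicate 2 or knockout replicate 3, 3 Paneth genes fell. Of 19 epithelial antimicrobial and acute-phase genes, 5 rose and 2 fell over the list alone, and camera gave adjusted p = 0.577. The antimicrobial lectin gene Reg3a fell from 62.9 ± 7.49 to 17.1 ± 6.51 CPM. The serum amyloid gene Saa1 rose from 1.12 ± 0.736 to 14.9 ± 13.2 CPM. The NADPH oxidase gene Nox1 had a log2 fold change of 5.06, from 0.861 ± 0.632 CPM in the controls. Nox1 stood at 1.67, 34.1 and 50.8 CPM in knockout replicates 1 to 3, against 0.748, 1.54 and 0.293 CPM in the controls. Its rise therefore lay mainly in knockout replicates 2 and 3. In this list 3 rose and 2 fell without control replicate 1, 11 rose and 8 fell without knockout replicate 1, and 5 rose and 1 fell without knockout replicate 2. With the replicate block, or without control replicate 2, control replicate 3 or knockout replicate 3, 0 rose and 1 fell.

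Tuft cell genes did not move alike in the knockouts. The list level was −0.03 in knockout replicate 1, −3.64 in replicate 2 and −2.70 in replicate 3, and 0 of 24 members passed the edgeR threshold over the list alone, with 2 at an unadjusted p and 0 by DESeq2, while limma-voom placed 21 lower in the same 6 libraries. Camera placed the list lower (adjusted p = 1.14e-09), with adjusted p = 0.436 with an estimated correlation. Without knockout replicate 1, 23 of the 24 members fell over the list alone. Enteroendocrine genes were higher by camera (adjusted p = 0.00230, and adjusted p = 0.436 with an estimated correlation), with 4 of 27 members rising over the list alone, among them the neurotensin gene Nts (31.9 ± 5.39 to 55.1 ± 6.96 CPM, SD, n = 3 each), and 0 with the replicate block. That count was 0 without control replicate 2 or 3 or knockout replicate 2 or 3, 7 without control replicate 1 and 9 without knockout replicate 1, the last 2 with 1 member lower, and the camera adjusted p was 0.0559 without knockout replicate 2. Goblet cell genes did not pass by camera (adjusted p = 0.147, and 0.0354, lower, without knockout replicate 2), and the mucus gene Fcgbp stood at 10379 ± 2187 and 10530 ± 1004 CPM (SD, n = 3 each).

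Markers of T cells, macrophages, B cells, smooth muscle and fibroblasts were higher by camera. Of 39 measured genes of T cells and intraepithelial lymphocytes, 16 rose over the list alone, among them Cd8a (20.2 ± 5.09 to 40.6 ± 12.3 CPM, SD, n = 3 each) and the granzyme gene Gzma (84.9 to 284 CPM). Of 20 macrophage and dendritic cell genes, 10 rose, among them the integrin gene Itgax (3.62 to 8.38 CPM). The most abundant members of the T cell and B cell lists, Gzma and Igha, were higher in each knockout than in any control. Those of the macrophage, smooth muscle and fibroblast lists did not go alike. Mertk overlapped between genotypes (147 and 171 CPM), Mylk was 1.07-fold higher (253 and 271 CPM), and Fbln1 was lower (300 and 216 CPM). The T cell level was 0.72, 1.41 and 0.70 in knockout replicates 1 to 3 and the macrophage level 1.35, 0.87 and 0.86. B and plasma cell genes had levels of 1.90, −0.18 and 0.37 in the same order, smooth muscle genes 2.46, −0.29 and 3.04, and fibroblast genes 2.31, −0.56 and 1.33. Camera gave adjusted p = 1.30e-16 for T cells, 2.41e-10 for macrophages, 0.00117 for B cells, 0.000183 for smooth muscle and 0.00236 for fibroblasts, and adjusted p = 0.436, 0.182, 0.577, 0.436 and 0.495 with an estimated correlation. Without knockout replicate 1, B cells (0.973), smooth muscle (0.102) and fibroblasts (0.577) did not pass. With the replicate block, 0 T cell and 5 macrophage genes were left. Without control replicate 2 or 3 or knockout replicate 2 or 3, 0 T cell genes passed, and without control replicate 1 and knockout replicate 1, 27 and 23 did. The macrophage count was 3 and 0 without control replicate 1 and 2, and 6 and 2 without knockout replicate 1 and 3.

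**Figure D4:**
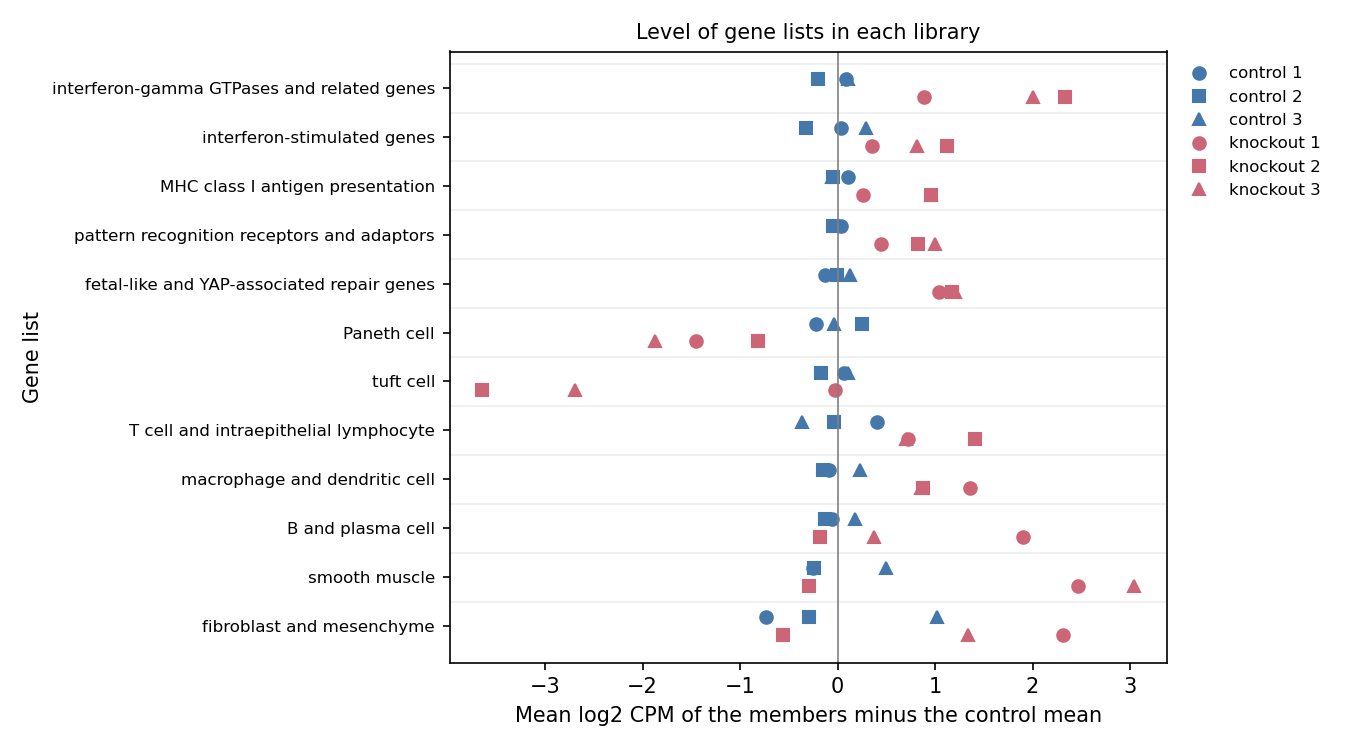
Mean log2 CPM of the members of 12 gene lists minus the control mean, in each library. The tuft cell level is near 0 in knockout replicate 1 and at −3.64 and −2.70 in replicates 2 and 3, while the interferon-gamma and repair lists lie above all controls in all 3 knockouts.

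Of the 54 lists, camera placed 22 higher and 8 lower at the preset correlation and 0 with an estimated one, and fry called 3, namely the repair list, macrophage and dendritic cells, and desmosomes and keratins. Cell cycle genes were higher by camera (adjusted p = 0.000335, and adjusted p = 0.679 with an estimated correlation), with levels of −0.27, 0.99 and 0.64 in knockout replicates 1 to 3 and 0 of 42 members past the threshold by edgeR (1 at an unadjusted p) or DESeq2. Genes of the unfolded protein response were higher (adjusted p = 0.00158, and adjusted p = 0.537 with an estimated correlation), with 0 of 28 members past it by edgeR over the list alone (7 at an unadjusted p) and 7 by DESeq2. Complement genes (adjusted p = 0.00272), endothelial genes (0.0181) and dissociation stress genes (0.0163) were higher, and each had adjusted p = 0.436 with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes (adjusted p = 4.51e-05), xenobiotic and retinoid genes (0.00439), circadian clock genes (0.00308) and cytosolic ribosomal protein genes (0.00972) were lower by camera, with adjusted p = 0.582, 0.436, 0.486 and 0.783 with an estimated correlation. The list levels of controls and knockouts overlapped in each of these lists. Ribosomal protein levels were −0.38, 0.29 and 0.09 in control replicates 1 to 3 and −0.44, 0.12 and −0.10 in knockout replicates 1 to 3. For oxidative phosphorylation, control replicate 1 (−0.136) lay below knockout replicates 2 and 3 (−0.125 and −0.111). In the clock list, 3 of 16 members fell over the list alone, among them the repressor gene Nr1d1 (154 ± 33.8 to 91.0 ± 17.2 CPM, SD, n = 3 each). The clock count was 0 without control replicate 2, control replicate 3 or knockout replicate 3, 1 without knockout replicate 2 (with 1 higher), and 10 without knockout replicate 1. Junction genes, desmosomes and keratins and villus tip genes, which were higher, and autophagy and adipocyte genes, which were lower, passed narrowly (adjusted p = 0.0479, 0.0479, 0.0438, 0.0460 and 0.0380), and had adjusted p = 0.112, 0.0793, 0.0793, 0.0840 and 0.0729 with the replicate block. The neutrophil list rested on Mmp9 alone. Without knockout replicate 1, the lists of complement (adjusted p = 0.0853), endothelium (0.338), dissociation stress (0.259), oxidative phosphorylation (0.0777), xenobiotics (0.218) and ribosomal proteins (0.857) did not pass, nor did endothelium and xenobiotics without control replicate 1 (0.0575 each) or ribosomal proteins without control replicate 2 (0.703). Without knockout replicate 2, cell cycle (0.211), the unfolded protein response (0.0571) and the clock (0.0982) did not. Among the narrow lists, junctions passed in 1 of the 6 sets with 1 library left out (without knockout replicate 1), desmosomes and keratins in 0, autophagy in 1 (without control replicate 3), villus tip in 3 (without control replicate 1 or knockout replicate 2 or 3) and adipocytes in 2 (without control replicate 1 or 2).

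Genes of polarity complexes, brush border and lipid absorption did not pass by camera. In the polarity list, Prkci was the 1 of 25 members past the threshold over the list alone, and camera gave adjusted p = 0.293. Brush border structure genes had adjusted p = 0.229 and 0 of 22 members past it by edgeR (3 at an unadjusted p) and 2 by DESeq2, and Vil1, which encodes villin, stood at 3143 ± 30.4 and 3266 ± 147 CPM (SD, n = 3 each). Lipid absorption genes had adjusted p = 0.228 (0.0320, higher, without control replicate 1), and Apob, the apolipoprotein of chylomicrons, stood at 12631 ± 1525 and 12692 ± 1268 CPM. In the list of brush border hydrolases and transporters (camera adjusted p = 0.536, and 0.00237, higher, without knockout replicate 1), 1 of 33 members rose and 2 fell over the list alone. The ferric reductase gene Cybrd1 rose from 2.81 ± 1.11 to 118 ± 109 CPM (SD, n = 3 each), and Slc1a1, a glutamate transporter, and the meprin gene Mep1a fell, the first from 147 ± 29.5 to 63.1 ± 6.36 CPM and the second by a log2 fold change of −1.14. Without knockout replicate 1, 16 rose and 4 fell, without knockout replicate 3 or with the replicate block 0 rose and 2 fell, and without any 1 of the other 4 libraries 0 rose and 1 fell.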

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

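The tests of this part, other than the setting with library totals, were chosen after the values were seen, and the 10 possible splits of 6 libraries into 3 and 3 are too few for a share below 0.05. An edgeR test of interaction between genotype and sex gave 102 genes with sex taken from Xist and Ddx3y, and 0 genes with the sexes of the series text, where 382 had an unadjusted p below 0.05. With sex by transcripts, the test rests on 1 knockout with Ddx3y (replicate 1) and 1 control with Xist (replicate 3), with 2 residual degrees of freedom, so it does not part sex from differences between single animals.

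Tuft cell genes were far lower in knockout replicates 2 and 3, with median differences from the control mean of −3.90 and −2.71 (log2). In knockout replicate 1 the median was −0.0038 (bootstrap interval over genes −0.15 to 0.08). This is 1 library, and the pattern was seen in these same values, so whether loss of Prkci acts by itself on these genes stays open. A control library with the wrong label would have control levels of Prkci, and knockout replicate 1 had 47.6% of the control mean (counting interval 43.2 to 52.3). A sex effect shared by both genotypes stays open, since 1 control had Xist. Its tuft median lay 0.14 above that of the 2 controls with Ddx3y, and the interval of 0.10 to 0.21 is over genes and holds no spread between animals. A sex effect in the knockouts alone (102 genes with an interaction) cannot be told apart from a difference of that 1 animal, and no such difference was tested. The labels describe the animals as co-housed and give no litter or cage for each.

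Interferon-related genes were higher in the knockouts together with leukocyte markers, so a higher share of leukocytes may account for part of this. The median log2 fold change of the interferon-gamma list exceeded the highest of the 3 leukocyte lists (1.18, macrophages and dendritic cells) by 0.486, with a bootstrap interval of −0.06 to 1.28 that includes 0. For interferon-stimulated and MHC class I genes pooled, the difference was −0.55 (−0.87 to −0.21), so their rise did not exceed that of the leukocyte markers. Neither comparison parts a change within epithelial cells from a change in cell shares, and an effect of genotype on either stays open. Pattern recognition genes and NF-kB targets were also higher together with leukocyte markers, at median log2 fold changes of 0.49 and 0.31. For these lists a higher share of leukocytes was not tested and stays open.

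Gm26917 and Gm42418 took a larger share of counts in the knockouts, which could come from less complete removal of ribosomal RNA. The share on mitochondrial ribosomal RNA genes was 0.652 times that of controls and on other annotated ribosomal RNA genes 1.55 times, which go in opposite directions, so this stays open. An effect of this share on the calls through the library sizes stays open too. All 9 called genes remained with protein-coding genes alone, but trimmed-mean scaling left little for that setting to move, and library totals alone gave 16 genes.

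For the count of changed genes, the real split gave 9 and the highest other 5. Here and below, the 1 of 10 splits that gave as many is the real split itself. Among the splits that part 3 numbered pairs, the others gave 0. For the lists moved by camera, 1 of 10 splits gave as many, with 30 in the real split and 25 in the highest other, so camera at the preset correlation called many lists in any split. For members past the threshold over the list alone, the real split and the highest other gave 20 and 0 for interferon-gamma genes, 16 and 12 for interferon-stimulated genes, 11 and 0 for MHC class I, 8 and 0 for pattern recognition, 11 and 0 for repair genes, 6 and 2 for Paneth cells, 16 and 0 for T cells, and 10 and 0 for macrophages and dendritic cells, and in each of these lists 1 of 10 splits gave as many. In some further lists the real split gave more than any other. It and the highest other gave 5 and 0 for the inflammasome list and 4 and 0 for enteroendocrine genes. They gave 6 and 3 for NF-kB targets, 7 and 6 for antimicrobial genes and 3 and 1 for hydrolases and transporters. In the lists that follow, another split gave as many members as the real one or more. The real split and the highest other gave 0 and 64 for cytosolic ribosomal proteins and 0 and 38 for cell cycle. They gave 0 and 16 for the unfolded protein response, 1 and 11 for fibroblasts and 6 and 7 for smooth muscle. For MHC class II they gave 1 and 5, for the clock 3 and 3, and for the polarity list 1 and 1.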

How the results depend on the processing

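The settings added after seeing the data were sex by Xist and Ddx3y, protein-coding genes alone, leaving out the 3 libraries whose Xist went against the series text, and the newer edgeR estimation. The count of 9 changed genes was 9 with DESeq2 size factors, the stricter filter or protein-coding genes alone, 6 against a fold of 1.5, 11 with sex by Xist and Ddx3y, and 10 with the newer estimation. It was 16 with library totals alone, 284 with no filter on low counts, 839 with DESeq2, 5 with limma-voom, 4 with sex from the series text as a covariate, 0 with the replicate block, and 0 with the males of the series text alone (2 against 2). By Xist, control replicate 3 and knockout replicate 3 of that last setting were female. Leaving out the 3 libraries whose Xist went against the series text left control replicate 1 as the only control, so no count of genes is given for it. With the block, edgeR gave 2500 genes at an unadjusted p below 0.05. Leaving out 1 library gave from 0 to 2700 genes, the lowest without control replicate 1, 2 or 3 or knockout replicate 3 and the highest without knockout replicate 1. Fewer samples are part of the construction of the settings that leave libraries out, and otherwise the cause was not tested. Without knockout replicate 1, both knockouts left were female by Xist, so genotype and sex are not parted there. Prkci kept its direction in each setting, with −1.22 and an adjusted p of 0.0102 with no filter, −1.23 and 9.91e-08 with DESeq2, and −1.33 to −1.06 with 1 library left out. The adjusted p of Prkci was past the threshold in these 2 settings and without knockout replicate 1. It ran from 9.91e-08 to 0.486 over the settings with more than 1 control. The 9 genes kept their direction in each of their 19 alternatives. Of the members past the threshold over the list alone, T cells went from 16 to 9 with library totals or protein-coding genes alone, to 1 and 0 with sex from the series text and by transcripts, and to 30 with no filter. Interferon-stimulated genes went from 16 to 3 and 7 with the 2 sex covariates and to 28 with DESeq2 or no filter, MHC class I from 11 to 7 with sex by transcripts, 17 with DESeq2 and 18 with no filter, macrophages from 10 to 6 with library totals or sex by transcripts, pattern recognition from 8 to 5 with limma-voom and 4 with sex by transcripts, and Paneth cells from 6 to 10 with library totals or no filter. With the males of the series text alone, 0 interferon-stimulated, T cell, macrophage and NF-kB genes, 2 pattern recognition and 3 MHC class I genes passed. Against a fold of 1.5, these counts were 0, 0, 0, 3, 4 and 3 in the same order. In these 2 settings, interferon-gamma genes kept 13 and 16 members, repair genes 10 and 9, and Paneth cells 10 and 5. The 30 gene lists that moved became 0 with an estimated inter-gene correlation and 3 with fry, and between 24 and 30 with 1 library left out. Apart from those named with their results, the replicate block changed no other call of a list.

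Of the 30 lists that had passed, 2 changed direction, B and plasma cell genes, with adjusted p from 1.08e-09 to 0.973 over the libraries left out and the change without knockout replicate 1, and cytosolic ribosomal proteins, lower in the full set and higher without the 3 libraries whose Xist went against the series text (adjusted p = 0.00519). Lists that had not passed also changed direction. Among them, exocrine pancreas, lower at 0.736, was higher without control replicate 1, 2 or 3 or knockout replicate 1 (0.0298, 0.00359, 0.00436 and 2.90e-05). Genes that changed sign were not called in any of the settings named here, and the cause was not tested. With library totals alone, the log2 fold change was −0.058 for Vil1, −0.10 for Apob, −0.090 for Fcgbp, −0.0092 for Mylk, −0.093 for Zg16 and −0.0077 for mt-Co1. With the males of the series text alone, the log2 fold change was 0.030 for Ifi27l2b, 0.16 for Olfm4, −0.10 for Fcgbp, −0.081 for Mertk, −0.19 for Zg16, −0.0036 for Hspa8 and 0.18 for Hist1h1c. With protein-coding genes alone, the log2 fold change was −0.0084 for Apob and −0.00094 for Zg16. With sex by Xist and Ddx3y as a covariate, the log2 fold change was 0.021 for Hist1h1c. With 1 library left out in turn, it ranged from −0.20 to 0.10 for Ifi27l2b, −0.084 to 0.11 for Apob, −0.53 to 0.41 for Olfm4, −0.10 to 0.22 for Fcgbp, −0.16 to 0.36 for Zg16, −0.041 to 0.45 for Cidec, −0.053 to 0.32 for mt-Co1 and −0.17 to 0.14 for Hist1h1c. Low counts limited Anxa10 and other genes near 0 in the controls, whose ratios rest on few reads.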

Other observations

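The genes of this part were chosen after their values were seen, from 10 genes linked to type 2 immunity and 6 of iron uptake, and no test of either set was run. Pla2g4c, a phospholipase, stood at 1186, 2671 and 2939 CPM in control replicates 1 to 3 and at 2262, 0.784 and 2.72 CPM in knockout replicates 1 to 3. Gsdmc2, a gasdermin gene with close copies, stood at 332 CPM in knockout replicate 1 and at 0.305 and 2.00 CPM in replicates 2 and 3, against 134, 298 and 336 CPM in the controls. Retnlb, a goblet cell antibacterial protein, stood at 12.1, 0.131 and 0.0400 CPM in knockout replicates 1 to 3, against 5.59, 3.58 and 14.4 CPM in the controls. Ang4, an angiogenin, stood at 460, 33.0 and 15.1 CPM in the knockouts, and Gsdmc3, Gsdmc4 and Sprr2a3 were also far lower in knockout replicates 2 and 3 than in replicate 1 (114, 293 and 533 CPM in replicate 1). The other 3 genes of the set differed from these. Itln1, an intelectin, stood at 192, 348 and 265 CPM in the knockouts, lowest in replicate 1, and Clca1, a goblet cell protease, at 3701, 2514 and 2731 CPM against 4126, 4419 and 5344 CPM in the controls. Mptx1 stood at 7.64 CPM in knockout replicate 1, below each control, and had 0 counts in replicates 2 and 3. By edgeR, none of the 10 passed in the comparison of genotypes over all genes tested (adjusted p = 0.731 for Pla2g4c), and by DESeq2 Clca1 did, with no adjusted p given for 4 of the others. Of 24 tuft genes, 0 in knockout replicate 1 were below a level of 0.5 times the lowest control, and 22 were in replicate 2 and 22 in replicate 3.

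Among the 6 iron uptake genes, Cybrd1, the duodenal ferric reductase, stood at 5.21, 223 and 127 CPM in knockout replicates 1 to 3, against 1.72, 2.79 and 3.93 CPM in the controls. Slc40a1, the iron exporter ferroportin, stood at 5.97, 382 and 409 CPM in the knockouts, against 3.04, 2.08 and 25.5 CPM in the controls. Slc11a2, an iron importer, stood at 82.4, 604 and 134 CPM in the knockouts, against 86.6, 72.6 and 81.2 CPM in the controls. The transferrin receptor gene Tfrc did not go with them, at 183, 438 and 245 CPM in the knockouts and 294, 327 and 361 CPM in the controls, and Heph, a ferroxidase, was 1.43-fold higher. Slc46a1, a folate and heme carrier, stood at 104, 188 and 213 CPM in the knockouts and at 116, 68.3 and 104 CPM in the controls. By edgeR none of the 6 passed over all genes tested, and by DESeq2 Cybrd1 and Slc40a1 did. Cybrd1 is also a member of the list of proximal small intestine genes. That list and the ileum list did not pass by camera (adjusted p = 0.0822 and 0.434). Both were higher by camera without knockout replicate 1 (adjusted p = 0.00246 and 0.0329). A difference in the intestinal segment sampled was not tested.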
